A study of Drosophila melanogaster with 12 samples.

How the data were processed

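Polyadenylated RNA of *Drosophila melanogaster* was sequenced in 12 libraries, which the labels place in 4 groups. Neuroblasts, the stem cells of the larval brain, were sorted by fluorescence from brains of late larvae reared at 29 °C and carrying dicer2 with a type I neuroblast driver (asense-Gal4) and a membrane-bound GFP, crossed either to an empty landing site (control, 2 libraries) or to an RNA interference (RNAi) line against *barc* (2 libraries). S2 cells, a cell line of embryonic, blood-cell-like origin, were kept in medium with 10% serum and treated for 7 days with double-stranded RNA against mCherry, a sequence that flies lack (control, 4 libraries), or against *barc* (4 libraries). All libraries were strand-specific (dUTP method) per the labels' protocols. The neuroblast libraries were made by hand with a KAPA kit and the S2 libraries on a robot with an NEB kit, so levels in the 2 systems were set side by side only through changes within each system. The strand setting of the authors' counting, the genome build and the annotation are not given in the sources used here. The submitters name in their processing notes BWA 0.6.1, TopHat 1.4.1, Cufflinks 1.3.0, HTSeq and DESeq with no role for each.

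The expression values are FPKM (fragments per kilobase of transcript per 1000000 mapped fragments) as the authors deposited them, 1 table of 14210 genes per library with the columns of a Cufflinks gene table and a confidence interval around each value. The authors also deposited 2 tables of their own comparisons with the columns of DESeq output. These hold, for each gene, the mean signal of each group (counts divided by size factors), the ratio of the group means, its log2 and a p-value with its adjusted p-value, all as deposited by the authors, and no value of a single library. No column of other samples was left unused (0 columns). No counts per library were used here, so limma on log FPKM was the test, and values of the authors' tables are named as theirs. Gene symbols and identifiers are those of the tables. Of the 14210 identifiers, 13575 are in the release 6 annotation of the fly genome, which was used for intron structure alone. Coordinates are given as the tables give them. The commonest difference from release 6 starts was 0 bases on arm 2L, 4112495 on 2R, 6900 on 3L, 4174278 on 3R and 105967 on X, so the tables' coordinates belong to an earlier build, which the sources used here do not name.

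The width of the confidence interval implies a number of fragments per gene, the square of 2 times the FPKM over the distance to the upper bound. Among genes of 1 transcript with fewer than 200 implied fragments, between 91.6% and 92.3% of these numbers per library lay within 0.02 of a whole number, so they served as a measure of depth. They summed to 30.4 and 27.1 M (M stands for 1000000) in the neuroblast controls, 48.7 and 42.0 M in the *barc* RNAi neuroblasts, 21.7, 28.6, 20.7 and 18.8 M in the S2 controls and 17.2, 14.6, 17.9 and 18.3 M in *barc* RNAi S2 cells. A single gene took at most 6.39% of the FPKM sum of any library (CR34335, neuroblast control 1).

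Replicates were compared before they were averaged, over genes with at least 10 implied fragments in each library of a pair. The chi-square per degree of freedom was 5.97 between the neuroblast controls, 12.4 between the *barc* RNAi neuroblast libraries, and 26.1, 70.3, 3.58 and 7.01 between S2 libraries 1 and 2 or 3 and 4 of the same group, so no pair was closer than sampling noise and none was treated as 1 library. The labels do not say that replicates came from separate cultures or cohorts of animals. The p-values therefore measure the spread between these libraries, which may be technical. In the sample descriptions the S2 libraries carry a first number, 1 for replicates 1 and 2 and 2 for replicates 3 and 4 of both groups, whose meaning the labels do not give. It was treated as a possible batch. All S2 results were recomputed within replicates 1 and 2, within replicates 3 and 4, and with this number as a block.

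Each system had its own fit, limma-trend on log2(FPKM + 1), over genes with a mean FPKM of at least 1 in that system. Genes with a failed or low-data estimate in a library of the fit were left out (47 in neuroblasts and 41 in S2 cells), a choice made after seeing the data. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are *barc* RNAi minus control on the log2(FPKM + 1) scale, which understates the change of genes with a low FPKM. The difference between the systems was tested as an interaction in 1 limma fit over all 4 groups. The groups, tests, alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 672 genes, of which 665 matched the tables and 12 were on more than 1 list. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Camera at an estimated correlation draws on the residual degrees of freedom, 2 in neuroblasts and 6 in the pooled S2 fit. It can therefore have little power here, and its power was not measured. A list that passed only at the preset correlation depends on that setting, and the second test does not argue against it.

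The genes named in the text are *barc*, the 10 with the largest rise and the 10 with the largest fall per system among called genes whose libraries do not overlap between the groups (genes with only a CG number left out where 10 named ones remained), up to 4 called members with the largest change per list (or the largest change where no member was called), the 10 genes called the same way in both systems with the largest smaller change, and the 5 genes per direction with the smallest p in the interaction test. Of these 184 genes, 62 overlap another gene in the tables. With no strand setting stated for the counting, their values are uncertain, as are those of near-identical copies such as the Hsp70B genes.

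The S2 replicate numbers are shared between the groups. Deviations from the group means of libraries with the same number correlated at 0.58, 0.59, 0.59 and 0.45, but each library also correlated with the other replicate of the same first number in the other group (0.33 to 0.62), so this pairing comes from the first number. Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum of 5 FPKM, rescaling to TPM, equal library medians, quantile normalisation, robust eBayes, 1 fit over all groups, the authors' adjusted p, the replicate block, the first-number fits and leaving out each library. Rescaling to TPM moved the median log2 fold change of all tested genes from -0.015 to 0.080 in neuroblasts and from -0.062 to 0.055 in S2 cells.

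On simulated data with 200 changed genes, the neuroblast fit recovered 100% of genes changed by 0.5, 1 or 2 on the log2 scale and called 0.276% of unchanged genes. The S2 fit recovered 15.5%, 86.2% and 97.4% of these sizes and called 0.0946% of unchanged genes. The interaction fit recovered 55.7% of changes of 1 and 94.7% of changes of 2 and called 0.164% of unchanged genes. Changes were placed only in genes of higher FPKM. The simulated noise was normal and independent between genes and libraries, with no shared effect of the first number. Recovery of genes with a low FPKM, and rates under such a shared effect, were therefore not measured. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.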

Results

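Transcript levels were measured by RNA sequencing in 2 fly systems in which *barc* had been depleted. The gene encodes barricade, the fly counterpart of the human splicing and elongation factor Tat-SF1. The first system was the type I neuroblast, the neural stem cell of the larval brain, sorted as GFP-bearing cells from control larvae (2 libraries) and from larvae with *barc* RNAi (2 libraries). The second was the S2 cell line after treatment with double-stranded RNA against mCherry (4 control libraries) or *barc* (4 libraries). The number of fragments implied by the deposited values ran from 14.6 M (M stands for 1000000, S2 *barc* RNAi replicate 2) to 48.7 M (neuroblast *barc* RNAi replicate 1), and both *barc* RNAi neuroblast libraries were deeper than both controls. Changes are log2 fold changes of log2(FPKM + 1), *barc* RNAi minus control, tested with limma, and errors of means are SDs over libraries.

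The targeted transcript was lower in every *barc* RNAi library than in every control of the same system. In neuroblasts *barc* (FBgn0037081, arm 3L, 21413483 to 21426267) fell from 90.2 ± 5.39 to 16.5 ± 2.02 FPKM (SD, n = 2 per group), a log2 fold change of -2.39 (SE 0.083, limma adjusted p = 5.9e-07). The neuroblast libraries stood at 86.4 and 94.0 FPKM in the controls and 15.1 and 17.9 FPKM after RNAi. In S2 cells it fell from 22.1 ± 1.39 to 4.46 ± 1.99 FPKM (n = 4 per group), a log2 fold change of -2.14 (SE 0.22, limma adjusted p = 6.7e-04), with -1.82 in replicates 1 and 2 and -2.46 in replicates 3 and 4. The authors' deposited table gave -2.64 in neuroblasts and -2.23 in S2 cells. The *barc* locus overlaps rgn and CG33288, so its level may include fragments of these genes.

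**Figure D1:**
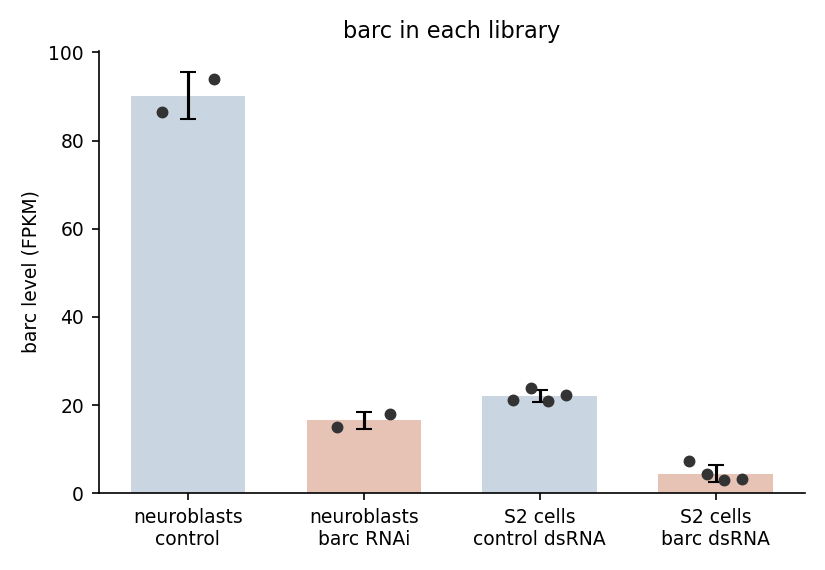
Level of *barc* in FPKM (linear axis from 0) in control and *barc* RNAi neuroblasts and S2 cells. Bars are means, error bars SDs and dots single libraries, and the 2 neuroblast *barc* RNAi libraries lie at 15.1 and 17.9 FPKM against 86.4 and 94.0 FPKM in their controls.

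The first comparison asked how the neuroblast transcriptome differed when *barc* was depleted. Arc1 (FBgn0033926, arm 2R, 10245432 to 10247799), which encodes a capsid-forming protein related to retrotransposon Gag, showed the largest rise on the log2(FPKM + 1) scale, from 6.23 ± 0.638 to 309 ± 99.7 FPKM (log2 fold change 5.39, SE 0.17, limma adjusted p = 3.7e-07, n = 2 per group). The cytochrome P450 gene Cyp4p2 (FBgn0033395, arm 2R, 5125035 to 5127336) rose from 0.433 ± 0.00572 to 33.3 ± 7.45 FPKM (4.57, SE 0.14), and the glutathione S-transferase gene GstE6 (FBgn0063494, arm 2R, 14293518 to 14294266) from 3.36 ± 0.499 to 94.2 ± 25.4 FPKM (4.43, SE 0.16). Pvf2 (FBgn0031888, arm 2L, 7069578 to 7084634), a ligand of the PDGF and VEGF family, rose from 0.587 ± 0.103 to 20.6 ± 4.55 FPKM (3.75, SE 0.14). Gadd45 (FBgn0033153, arm 2R, 3136668 to 3138160), a gene of stress and DNA damage responses, rose from 0.920 ± 0.189 to 16.8 ± 2.68 FPKM (3.21, SE 0.13).

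The other named genes with the largest rises were the sodium/proton antiporter gene Nha2 (3.99, SE 0.15), the thioester protein gene TepIV (3.73, SE 0.18), GstD5 (3.58, SE 0.27), Rcd-1r (3.15, SE 0.091) and Syn2 (3.07, SE 0.18). The authors' deposited table, without that added 1, gave higher values for Nha2 (6.80), Cyp4p2 (6.32), GstD5 (5.90) and Syn2 (5.83) than for Arc1 (5.71). Among these 10 genes the highest limma adjusted p was 3.0e-05 (GstD5). Cyp4p2, Nha2 and Rcd-1r overlap other genes, and GstE6 and GstD5 have close paralogs beside them, so their levels are uncertain. By FPKM, the largest fall after RNAi among named genes was that of RpS6 (FBgn0261592, arm X, 7793653 to 7795362), which encodes a protein of the small ribosomal subunit, from 30.6 ± 1.98 to 4.23 ± 0.893 FPKM (-2.60, SE 0.11). The authors' deposited table, made from counts, gave -0.34 for this gene, with mean signals of 83031 and 65471. RpS14a had lower signals there (48297 and 29317) but stood at 2129 and 1226 FPKM. The FPKM of RpS6 thus did not follow its counts, which argues against a fall of this size. Leaving out *barc* itself (-2.39), the next named genes were fog, a secreted ligand of gastrulation (-2.21, SE 0.12), IM23 (-2.17, SE 0.058), the germline RNA helicase gene vas (-2.10, SE 0.12), the endocytosis gene stnB (-1.72, SE 0.14) and the antimicrobial peptide gene CecA1 (-1.66, SE 0.071). Scgdelta (-1.58, SE 0.087), AnnIX (-1.49, SE 0.14), the ion channel gene rpk (-1.48, SE 0.12) and GNBP3 (-1.42, SE 0.13) also fell, and the highest limma adjusted p of these 10 was 1.2e-04 (AnnIX). AnnIX overlaps r-l and vas overlaps vig.

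Genes of neuroblast identity went both ways and most did not pass the test. Of 15 tested, 3 rose and 3 fell, among them the stem cell repressor gene dpn (170 ± 2.90 to 132 ± 4.57 FPKM, -0.37, SE 0.051), D (-0.49, SE 0.086), insc (-0.27, SE 0.051) and esg (0.59, SE 0.15). Levels of ase (79.1 and 77.0 FPKM), wor (139 and 142 FPKM) and mira (912 and 852 FPKM in control and *barc* RNAi) did not pass. In asymmetric division, 6 of 28 genes rose and 8 fell, including jar (-0.39, SE 0.064), l(2)gl (-0.38, SE 0.053) and Khc-73 (0.31, SE 0.075). Of 9 temporal factors 0 rose and 1 fell (limma, 0 and 1 at an unadjusted p under 0.05), the RNA-binding protein gene CG17838, known as Syncrip (-0.18, SE 0.054, authors' adjusted p = 0.263). Among 5 markers of type II neuroblasts and their intermediate progenitors, 1 rose (fd59A, 0.52, SE 0.12) and 1 fell (erm, -0.43, SE 0.12). In the Notch pathway 5 of 15 genes rose and 1 fell, with HLHmbeta (0.53, SE 0.084), mib1 (0.50, SE 0.083) and kuz (0.40, SE 0.066) as examples. None of these 5 lists passed camera (adjusted p between 0.284 and 0.969). By an adjustment over each list by itself, the counts were the same except for the temporal factors, of which 0 rose and 0 fell.

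Markers of other cell types were mostly low in the sorted cells. The fit tested 11 of 23 neuron markers, 6 of 15 glial markers, 3 of 14 hemocyte markers and 1 of 9 fat body markers. Of the neuron markers 5 rose and 2 fell, led by unc-13 (7.55 ± 0.840 to 23.2 ± 5.65 FPKM, 1.49, SE 0.14) and fne (0.59, SE 0.077), while nab fell (293 ± 0.662 to 229 ± 8.51 FPKM, -0.36, SE 0.050). Both glial markers that passed fell, the glutamate transporter gene Eaat1 from 76.0 ± 2.23 to 38.9 ± 2.42 FPKM (-0.95, SE 0.061) and nrv2 from 124 ± 5.59 to 88.6 ± 7.70 FPKM (-0.49, SE 0.068). The hemocyte markers Sr-CI (-0.62, SE 0.11) and crq (-0.19, SE 0.064) fell, and the fat body marker Lsp1gamma stood at 2.88 and 2.98 FPKM (limma adjusted p = 0.802). Neither the neuron nor the glial list passed camera (adjusted p = 0.284 for both), and the other lists had fewer than 5 tested genes. Counts adjusted over the list alone were the same for these lists.

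Glycolysis genes rose together in *barc* RNAi neuroblasts. Of 12 tested, 10 rose and 0 fell (limma, 10 and 0 at an unadjusted p under 0.05), with a median log2 fold change of 0.47. ImpL3 (FBgn0001258, arm 3L, 6252592 to 6255793), the lactate dehydrogenase gene, rose from 6.33 ± 2.21 to 52.01 ± 20.4 FPKM (2.83, SE 0.25, limma adjusted p = 7.9e-05), Tpi from 116 ± 7.76 to 231 ± 21.0 FPKM (0.99, SE 0.073) and Gapdh1 from 220.2 ± 16.6 to 389 ± 8.83 FPKM (0.82, SE 0.061). The list passed camera (adjusted p = 7.9e-06) but not with the estimated correlation (adjusted p = 0.867 with an estimated correlation). With 2 residual degrees of freedom, not passing this second test does not argue against a shared rise. Of 25 genes of oxidative phosphorylation 4 rose and 8 fell, among them ox (-0.68, SE 0.061) and SdhB (-0.43, SE 0.070). That list had a median of 0.04, a mean of -0.08 and a camera direction of lower (adjusted p = 0.783). When adjusted within each list, these counts were the same.

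Genes of the p53, DNA damage and apoptosis list rose more often than they fell. Of 26 tested, 13 rose and 3 fell, with Gadd45, the DNA repair gene rad50 (39.4 ± 2.11 to 78.9 ± 8.63 FPKM, 0.98, SE 0.078), mus205 (0.93, SE 0.11) and Corp (0.84, SE 0.066) at the top. The median was 0.26 and the list passed camera (adjusted p = 0.0042), but not with the estimated correlation (adjusted p = 0.867 with an estimated correlation). The stress kinase (JNK) list had Gadd45 and GstD1 (0.83, SE 0.068) among 2 of 12 genes that rose and the catalase gene Cat as 1 that fell (-0.16, SE 0.050), with camera adjusted p = 0.284. Of 19 heat shock genes 5 rose and 2 fell, with Hsp22 rising from 190.5 ± 12.4 to 587 ± 23.3 FPKM (1.62, SE 0.060) and Hsp70Bb falling (-0.34, SE 0.089). Hsp22 overlaps Hsp67Bb and has no value in the authors' tables, so its level is uncertain. Of 14 genes of the unfolded protein response 5 rose and 5 fell, including Xbp1 (0.49, SE 0.054) and sip3 (-0.86, SE 0.079). Camera gave adjusted p = 0.302 and 0.820 for these 2 lists, and the unfolded protein response had a median of -0.11, a mean of 0.01 and a camera direction of higher. Among 6 immune effector genes, 5 fell and 1 rose, with CecA1, CecC (-1.10, SE 0.10) and CecA2 (-0.86, SE 0.12) as antimicrobial peptide genes. The median was -0.73 and the list passed camera (adjusted p = 0.027), but not with the estimated correlation (adjusted p = 0.867 with an estimated correlation) or without the filter on low values (adjusted p = 0.194, from 2.0e-04 to 0.194 over the alternatives tested by camera with the preset correlation). Counts adjusted over the list alone differed for the unfolded protein response (6 rose and 5 fell) and the JNK list (2 rose and 0 fell) and were the same for the others.

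Cell cycle lists showed small changes in both directions. Of 45 genes of the G1/S transition and replication 7 rose and 8 fell, including RpA-70 (0.35, SE 0.052), RnrL (0.32, SE 0.048) and Sld5 (-0.36, SE 0.057). Of 75 genes of G2/M and mitosis 7 rose and 25 fell, with the centrosome genes cnn (0.63, SE 0.075) and ana2 (0.53, SE 0.058) rising and gammaTub23C (-0.50, SE 0.051) and mars (-0.43, SE 0.052) falling. Neither list passed camera (adjusted p = 0.783 and 0.284). Adjusted over the list alone, 6 rose and 8 fell in the first and 7 rose and 26 fell in the second. The median of the first list was -0.01 and its mean -0.001, while camera put it higher.

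Among the partners of U2 snRNP, the splicing particle with which Tat-SF1 works, 4 of 16 genes rose and 6 fell. Beside *barc* itself these included CG13900, known as Sf3b3 (211 ± 4.93 to 402 ± 1.26 FPKM, 0.93, SE 0.048), CG13298 (-0.27, SE 0.047, but -0.17 in the authors' table) and CG11985 (-0.65, SE 0.062), for which the authors' deposited table gave -0.06 (adjusted p = 0.656). Of 39 other spliceosome genes 8 rose and 7 fell, with Prp31 (0.65, SE 0.064) and l(3)72Ab (0.63, SE 0.074) rising and SmG (-0.38, SE 0.055) falling. Of 13 genes of the exon junction complex and nonsense-mediated decay 4 rose and 4 fell, among them Gadd45, a transcript kept low by that decay, mago (-0.52, SE 0.050) and Smg6 (0.35, SE 0.066). In transcription elongation 3 of 21 genes rose and 3 fell, and Cdk9, the kinase of the elongation factor P-TEFb, fell from 33.8 ± 0.151 to 15.03 ± 0.594 FPKM (-1.12, SE 0.061). No list of these 4 passed camera (adjusted p between 0.751 and 0.783). Median and mean had different signs in the exon junction list (-0.003 and 0.21) and in transcription elongation (0.05 and -0.04), and camera put both higher. By an adjustment over each list by itself, 5 rose and 4 fell in the exon junction list and 2 rose and 3 fell in transcription elongation, and the other counts were the same.

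Genes of cytosolic ribosomal proteins fell more often than they rose. Of 89 tested, 44 fell and 7 rose, including RpS14a (-0.80, SE 0.059), RpS5b (-0.89, SE 0.16) and, in the other direction, RpL37b (0.528 ± 0.0411 to 6.42 ± 1.55 FPKM, 2.26, SE 0.16), a paralog that was low in the controls. The median was -0.15, but -0.05 after rescaling to TPM and -0.02 with quantile normalisation, and the list passed camera (adjusted p = 1.5e-04), but not with the estimated correlation (adjusted p = 0.867 with an estimated correlation), with quantile normalisation (adjusted p = 0.514) or in 1 fit over all 4 groups (adjusted p = 0.0611), and the range over the alternatives tested by camera with the preset correlation was 2.5e-07 to 0.514. Of 28 ribosome biogenesis genes 1 rose and 10 fell, such as Nop60B (-0.34, SE 0.047) and CG7637 (-0.59, SE 0.090, but -0.18 in the authors' table), and of 29 proteasome genes 0 rose and 7 fell (limma, 1 and 11 at an unadjusted p under 0.05), such as Pros26 (-0.26, SE 0.053). Camera gave adjusted p = 0.284 for both. When adjusted within each list, 9 rose and 48 fell for the ribosome, 0 rose and 6 fell for the proteasome, and ribosome biogenesis was the same.

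Over all genes, limma called 2888 of 6732 in neuroblasts (1283 higher and 1605 lower after *barc* RNAi), of which 117 were at least 2-fold higher and 66 at least 2-fold lower. The median absolute log2 fold change of called genes was 0.34. After rescaling to TPM the call was 3108 genes, 2067 higher and 1041 lower, so the balance of small changes depended on the scaling. The authors' deposited table calls 3101 genes (1608 higher and 1493 lower), and 2377 of the 2381 called by both had the same direction. With 2 libraries per group, leaving out control 1 or control 2 left 1847 or 1897 genes, and 1 fit over all 4 groups, which shares the spread with S2 cells, called 356. Of 108 called genes named by the rule, 15 lost the call when 1 library was left out, among those above esg (adjusted p = 0.116 without control 1), erm (0.180 without control 2), fd59A (0.0900 without control 1), Khc-73 (0.0721 without control 1), CG17838 and crq (0.210 and 0.223 without *barc* RNAi 1), Cat (0.133 without control 1) and Hsp70Bb (0.105 without control 2).

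The second comparison asked the same of S2 cells, where the samples carry a first number that splits them into replicates 1 and 2 and replicates 3 and 4. Cyp6d2 (FBgn0034756, arm 2R, 18540078 to 18542032), a cytochrome P450 gene, showed the largest rise among named genes on this scale, from 1.03 ± 0.219 to 65.7 ± 15.2 FPKM (5.02, SE 0.18, limma adjusted p = 3.9e-06, n = 4 per group), with 5.24 in replicates 1 and 2 and 4.79 in replicates 3 and 4. Heat shock genes made up 7 of the 10 named genes with the largest falls. The small chaperone gene Hsp26 (FBgn0001225, arm 3L, 9369518 to 9370527) fell from 1678 ± 366 to 199 ± 51.5 FPKM (-3.08, SE 0.22, limma adjusted p = 2.8e-04), with -3.16 and -3.003 in these 2 pairs of replicates. The lactate dehydrogenase gene ImpL3 fell from 379.8 ± 102 to 62.5 ± 38.8 FPKM (-2.78, SE 0.44, limma adjusted p = 0.0039), with -3.96 and -1.60. The spindle orientation gene insc (FBgn0011674, arm 2R, 16708771 to 16723569) rose from 1.80 ± 0.120 to 22.8 ± 13.5 FPKM (2.89, SE 0.38, limma adjusted p = 0.0018), with 3.71 and 2.07.

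The S2 libraries differed by this first number as well as by treatment. In a principal component analysis the first component took 61.0% of the variance and the second 27.7%. On the first, the controls stood at -18.8, -21.9, -38.6 and -26.5. There *barc* RNAi replicates 1 and 2 stood at 52.5 and 50.4 and replicates 3 and 4 at 0.225 and 2.72, so neither component separated treatment from the first number. On the second, controls 1 and 2 stood at -28.4 and -28.9 and controls 3 and 4 at 1.22 and 12.6, and *barc* RNAi replicates 1 and 2 at -8.34 and -8.75 and replicates 3 and 4 at 29.6 and 31.01. Log2 fold changes in replicates 1 and 2 and in replicates 3 and 4 had a Pearson r of 0.78 and a Spearman rho of 0.73 across 7319 genes, which are not independent replicates, with median absolute values of 0.47 and 0.25. Of 806 genes called in both pairs 789 had the same direction.

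**Figure D2:**
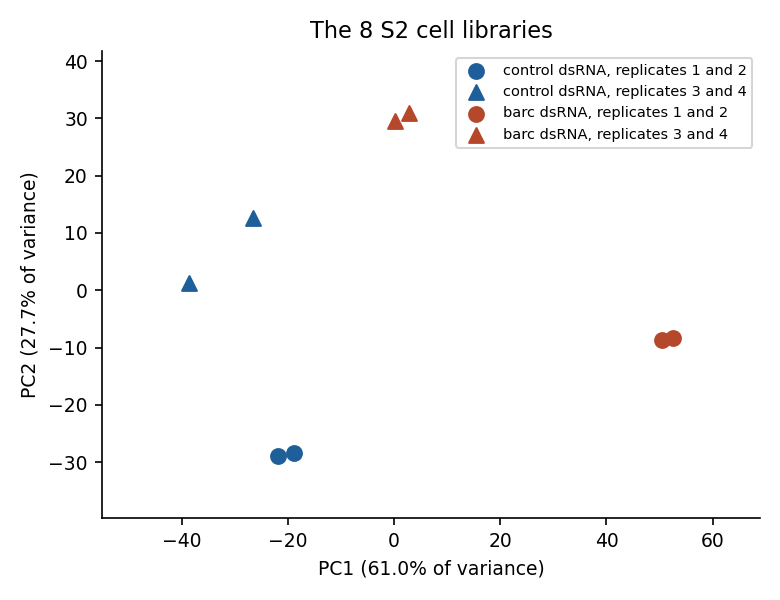
First and second principal components of the 8 S2 libraries (61.0% and 27.7% of the variance), with controls and *barc* RNAi in different colours, circles for replicates 1 and 2 and triangles for replicates 3 and 4. The second component places controls 1 and 2 at -28.4 and -28.9 and controls 3 and 4 at 1.22 and 12.6.

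Further named genes with large rises in S2 cells were Taf12L (4.08, SE 0.80), t-cup (2.95, SE 0.72), Tektin-A (2.89, SE 0.59), the innexin gene ogre (2.70, SE 0.29), the protease gene Jon66Ci (2.64, SE 0.29), the Notch pathway gene spdo (1.72 ± 0.967 to 14.6 ± 2.62 FPKM, 2.57, SE 0.24), the sulfatase gene Sulf1 (2.51, SE 0.48) and atilla (2.36, SE 0.75). Their changes in replicates 1 and 2 and in replicates 3 and 4 were 3.95 and 4.20 for Taf12L, 3.86 and 2.03 for t-cup, 4.05 and 1.74 for Tektin-A, 3.34 and 2.07 for ogre, 2.69 and 2.45 for spdo and 3.69 and 1.33 for Sulf1. For atilla it was 3.83 in replicates 1 and 2, and the gene was below the filter in replicates 3 and 4. The authors' table gave higher values for Tektin-A (8.19) and atilla (6.22) than for Cyp6d2 (6.05). The highest limma adjusted p of the 10 was 0.0465 (atilla). Taf12L, t-cup, insc, ogre, spdo and Sulf1 overlap other genes. Beside the heat shock genes and ImpL3, the gene cu fell from 42.7 ± 6.52 to 4.22 ± 2.33 FPKM (-3.18, SE 0.31, with -3.62 and -2.73) and hoe1 from 34.6 ± 2.64 to 6.61 ± 6.69 FPKM (-2.84, SE 0.69, with -4.17 and -1.50).

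Of 19 heat shock genes 15 fell and 0 rose in S2 cells (limma, 16 and 0 at an unadjusted p under 0.05), with a median log2 fold change of -2.33. Hsp70Bb fell from 174 ± 64.6 to 17.7 ± 9.60 FPKM (-3.31, SE 0.41), Hsp68 from 209 ± 48.4 to 24.0 ± 9.24 FPKM (-3.12, SE 0.28), Hsp27 by a log2 fold change of -3.02 (SE 0.36) and Hsp22 by -2.94 (SE 0.29). The Hsp70B copies Hsp70Bb, Hsp70Bc (-3.06, SE 0.42) and Hsp70Ba (-2.84, SE 0.25) share sequence, and their separate values are uncertain. Hsp22 overlaps Hsp67Bb and Hsp68 overlaps CG6000. The list passed camera (adjusted p = 1.5e-09, with 5.3e-05 in replicates 1 and 2 and 1.9e-17 in replicates 3 and 4) but not with the estimated correlation (adjusted p = 0.625 with an estimated correlation). Glycolysis genes fell, 7 of 11 with 0 rising (limma, 10 and 0 at an unadjusted p under 0.05), with a median of -0.66. Pfk, the phosphofructokinase gene (-1.48, SE 0.31), Eno (-1.08, SE 0.15) and Pgi (-0.93, SE 0.15) followed ImpL3, and camera gave an adjusted p = 7.9e-04, with 0.0015 and 0.0016 in the 2 pairs of replicates and adjusted p = 0.625 with an estimated correlation. Of 25 genes of oxidative phosphorylation 0 rose and 2 fell (limma, 0 and 6 at an unadjusted p under 0.05), SdhA (-0.86, SE 0.23) and SdhC (-0.68, SE 0.20). Camera gave an adjusted p = 0.118 for that list, with 9.9e-04 in replicates 1 and 2 (adjusted p = 0.462 with an estimated correlation) and 0.676 in replicates 3 and 4. Adjusted over the list alone, 10 glycolysis genes and 0 genes of oxidative phosphorylation fell, and the heat shock counts were the same.

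Genes of the p53, damage and apoptosis list and of the JNK list rose more often than they fell in S2 cells. Of 24 genes of the p53, damage and apoptosis list 7 rose and 2 fell, with a median of 0.38, among them the pro-apoptotic genes rpr (20.3 ± 5.40 to 100.4 ± 38.4 FPKM, 2.20, SE 0.28) and W, known as hid (2.14, SE 0.30), and the repair genes rad50 (1.45, SE 0.35) and nbs (1.10, SE 0.25). It passed camera (adjusted p = 0.024, with 0.0065 in replicates 1 and 2 and 0.045 in replicates 3 and 4) but not with the estimated correlation (adjusted p = 0.632 with an estimated correlation) or without the filter on low values (adjusted p = 0.0502, from 0.0059 to 0.0502 over the alternatives tested by camera with the preset correlation), and its median was 0.24 and 0.25 without *barc* RNAi 1 and 2. Of 15 JNK and stress genes 4 rose and 0 fell (limma, 5 and 1 at an unadjusted p under 0.05), with rpr, the cytokine gene upd3 (1.92, SE 0.21) and GstE1 (1.60, SE 0.25). The median was 0.60, with 0.68 in replicates 1 and 2 and 0.30 in replicates 3 and 4. Camera gave an adjusted p = 0.019, with 0.0098 and 0.015 in the 2 pairs of replicates and adjusted p = 0.625 with an estimated correlation. Of 14 genes of the unfolded protein response 1 rose (crc, 0.64, SE 0.12) and 2 fell, sip3 (-0.86, SE 0.12) and Gp93 (-0.71, SE 0.15), with the authors' adjusted p = 0.0548 for crc and 0.0855 for Gp93. Of 20 immune effector genes 2 rose and 2 fell, such as TotA (1.90, SE 0.53) and CecC (-0.84, SE 0.13, authors' adjusted p = 0.164). Camera gave adjusted p = 0.979 and 0.402 for these 2 lists. By an adjustment over each list by itself, 9 rose and 2 fell for p53, 4 rose and 1 fell for JNK, 0 rose and 1 fell for immune effectors, and the unfolded protein response was the same.

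In S2 cells 6 of 15 neuroblast identity genes and 26 of 28 genes of asymmetric division passed the filter. Of the 6 neuroblast identity genes 2 rose and 1 fell, insc, the receptor gene N (15.5 ± 1.24 to 44.9 ± 12.1 FPKM, 1.44, SE 0.18) and brat (-0.39, SE 0.11, authors' adjusted p = 0.285). In asymmetric division 3 of 26 genes rose and 2 fell, with insc, zip (0.78, SE 0.21) and pon (-0.82, SE 0.16), and of 2 type II markers 1 rose (fd59A, 1.82, SE 0.27) and 0 fell (limma, 1 and 1 at an unadjusted p under 0.05). In the Notch pathway 1 of 9 genes rose (N) and 1 fell (the ligand gene Ser, -1.61, SE 0.43). These lists did not pass camera in the pooled fit where tested (adjusted p between 0.129 and 0.637). Neuroblast identity stood at 0.031 in replicates 1 and 2 (adjusted p = 0.462 with an estimated correlation) and 0.374 in replicates 3 and 4. Of 8 temporal factors 2 rose, the ecdysone receptor gene EcR (0.70, SE 0.16) and br (0.66, SE 0.17), with a median of 0.55. Camera gave an adjusted p = 0.024, with 0.0084 in replicates 1 and 2 and 0.708 in replicates 3 and 4, and adjusted p = 0.789 with an estimated correlation. That call also ended without control 2 (0.0516), without control 3 (0.0776), with no filter (0.157) and with a minimum of 5 FPKM (0.0752), in a range of 0.0029 to 0.708 over the alternatives tested by camera with the preset correlation. When adjusted within each list, 3 temporal factors rose and 1 type II marker rose and 1 fell, and the other counts were the same.

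Of 7 neuron markers tested in S2 cells 3 rose and 0 fell (limma, 5 and 0 at an unadjusted p under 0.05), with unc-13 (15.5 ± 7.42 to 66.8 ± 23.4 FPKM, 2.13, SE 0.42), Nrg (1.13, SE 0.19) and jim (0.67, SE 0.18), and a median of 0.83. The median was 1.18 in replicates 1 and 2, and 0.48 in replicates 3 and 4, where 0 of 7 rose and 0 fell. The list passed camera (adjusted p = 0.0093, with 0.0032 and 0.045 in the 2 pairs of replicates) but not with the estimated correlation (adjusted p = 0.625 with an estimated correlation). Of 10 glial markers 2 rose (ogre and Gs2, 1.74, SE 0.26) and 1 fell (hoe1). Hemocyte markers, of which 12 of 14 were tested in this blood-cell-like line, included 1 that rose (He, 1.70, SE 0.54) and 3 that fell, the collagen genes vkg (619 ± 33.5 to 222 ± 42.4 FPKM, -1.49, SE 0.15) and Cg25C (-1.42, SE 0.16) and the matrix gene Ppn (-1.11, SE 0.25). Camera gave adjusted p = 0.591 and 0.960 for these 2 lists, and the hemocyte list had a median of 0.16, a mean of -0.10 and a camera direction of lower. Of 2 fat body markers 0 passed (limma, 1 at an unadjusted p under 0.05), with alpha-Est7 at 38.6 ± 17.6 and 113 ± 71.7 FPKM (adjusted p = 0.0744). That gene was called in the authors' table (adjusted p = 7.7e-09), with the replicate block (adjusted p = 0.0021) and without *barc* RNAi 3 (0.0390) or 4 (0.0447), in a range of 7.7e-09 to 0.177 over all alternatives. Within replicates 3 and 4 both fat body markers were called higher. Within replicates 1 and 2 both were also called, 1 higher and 1 lower. Adjusted over the list alone, 5 neuron markers rose and 0 fell, 1 fat body marker rose, and the glial and hemocyte counts were the same.

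The 2 cell cycle lists fell in replicates 1 and 2 and did not pass as lists in replicates 3 and 4. Of 45 genes of G1/S and replication 1 rose and 6 fell in the pooled fit, such as the ribonucleotide reductase gene RnrS (-1.25, SE 0.40), the licensing gene Cdc6 (-1.09, SE 0.23) and, in the other direction, RpA-70 (1.14, SE 0.31). Of 75 genes of G2/M and mitosis 2 rose and 10 fell, such as the phosphatase gene stg (-1.43, SE 0.33), CycA (-1.34, SE 0.41) and Incenp (-1.08, SE 0.32). Within replicates 1 and 2, 36 of the first list fell and 2 rose, and 57 of the second fell and 9 rose (camera adjusted p = 9.8e-05 for both, and adjusted p = 0.535 and 0.462 with an estimated correlation), with medians of -0.71 and -0.76. Within replicates 3 and 4, 2 of the first list rose (RpA-70, 0.73, and RnrL, 0.55) and 1 of the second fell (stg, -0.99) by limma, and the medians were 0.09 and 0.05 (camera adjusted p = 0.646 and 0.736). The effect differed between the 2 pairs by a median of 0.82 and 0.88 (camera adjusted p = 1.5e-08 and 8.5e-11, and adjusted p = 0.364 and 0.275 with an estimated correlation). The pooled lists had medians of -0.33 and -0.36 and camera adjusted p = 0.029 and 0.046, each with adjusted p = 0.971 with an estimated correlation. The G1/S call ended without control 2 (0.0619), *barc* RNAi 1 (0.122) or *barc* RNAi 2 (0.103) and with a minimum of 5 FPKM (0.0752), in a range of 9.8e-05 to 0.646 over the alternatives tested by camera with the preset correlation. That of G2/M ended in the replicate block (0.0604), without control 1 (0.0795), 2 (0.0518) or 4 (0.186), *barc* RNAi 1 (0.169) or 2 (0.140) and with a minimum of 5 FPKM (0.0936), in a range of 9.8e-05 to 0.736 over the same alternatives. By an adjustment over each list by itself, 0 rose and 3 fell in G1/S and 0 rose and 0 fell in G2/M, where 2 and 28 had an unadjusted limma p under 0.05.

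Among U2 snRNP genes in S2 cells, *barc* and CG11985 (-0.92, SE 0.17, authors' adjusted p = 0.143) fell and CG3605 rose (0.28, SE 0.088), 3 of 16 tested, and the call of CG3605 ended in the replicate block (adjusted p = 0.0682) and in the authors' table (0.384). Of 40 other spliceosome genes 6 rose and 4 fell, with CG7757 (0.72, SE 0.11), ncm (0.72, SE 0.15) and x16 (-0.77, SE 0.19), and the list had a median of -0.06, a mean of -0.01 and a camera direction of higher. Of 13 genes of the exon junction complex and decay 0 rose and 0 fell (limma, 2 and 3 at an unadjusted p under 0.05), with Smg6 showing the largest difference (0.84, adjusted p = 0.109, called in the authors' table with 3.1e-04, in the replicate block with 0.0259 and without *barc* RNAi 3 with 0.0427). In transcription elongation 1 of 22 genes rose and 2 fell, Cdk9 from 26.3 ± 3.04 to 12.2 ± 1.01 FPKM (-1.04, SE 0.12) and CG3508 (-0.45, SE 0.096, authors' adjusted p = 0.300). Neither these 4 lists nor the proteasome, with Rpn5 (0.55, SE 0.14, authors' adjusted p = 0.0602) as 1 of 30 genes that rose and 0 that fell (limma, 2 and 2 at an unadjusted p under 0.05), passed camera (adjusted p between 0.620 and 0.874). In replicates 3 and 4 alone the proteasome stood at 0.015 (adjusted p = 0.891 with an estimated correlation). Asymmetric division had a median of -0.01 and a mean of 0.05. When adjusted within each list, 8 rose and 8 fell for other spliceosome genes, 0 rose and 2 fell for U2 snRNP, 0 passed for the proteasome, and the other counts were the same.

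Ribosome biogenesis genes rose in S2 cells, 9 of 28 with 0 falling (limma, 16 and 1 at an unadjusted p under 0.05) and a median of 0.37. Examples were l(2)k09022 (0.98, SE 0.17), mod (110.1 ± 30.9 to 206 ± 8.67 FPKM, 0.93, SE 0.17), Nopp140 (0.86, SE 0.20) and the RNA polymerase I gene RpI1 (0.65, SE 0.085). The list passed camera (adjusted p = 3.7e-04, with 0.0098 and 4.9e-04 in the 2 pairs of replicates) but not with the estimated correlation (adjusted p = 0.625 with an estimated correlation). Cytosolic ribosomal protein genes fell, 15 of 88 with 3 rising and a median of -0.28 (-0.15 after rescaling to TPM and -0.11 with quantile normalisation), such as RpL34b (-1.69, SE 0.30), RpS15 (-1.35, SE 0.24) and RpS19a (-0.98, SE 0.20). Camera gave an adjusted p = 0.024, with 0.021 and 0.024 in the 2 pairs of replicates and adjusted p = 0.971 with an estimated correlation. That call ended with quantile normalisation (0.317) and without *barc* RNAi 1 (0.110), *barc* RNAi 2 (0.0939) or control 3 (0.216), in a range of 0.0024 to 0.317 over the alternatives tested by camera with the preset correlation. Adjusted over the list alone, 2 rose and 15 fell for the ribosome and ribosome biogenesis was the same.

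Over all genes, limma called 2030 of 7603 in S2 cells (876 higher and 1154 lower), of which 355 were at least 2-fold higher and 345 at least 2-fold lower, with a median absolute log2 fold change of 0.80. After rescaling to TPM it called 1748 (932 higher and 816 lower). The authors' deposited table calls 2054 (1379 higher and 675 lower), and 1164 of the 1165 called by both had the same direction. With the first number as a block the count was 3496 and held all 2030. Replicates 1 and 2 alone gave 5460, with 2017 of 2021 pooled calls also called the same way, and replicates 3 and 4 alone gave 927, with 705 of 2009 called and all 2009 in the same direction. Since the pooled fit holds these same libraries, a shared direction with its calls is partly built in. Leaving out control 1, control 2, *barc* RNAi 1 or *barc* RNAi 2 left 1253, 1146, 1154 or 1104 genes. Of 92 called genes named by the rule 28 lost the call when 1 library was left out. Those used above are given with the highest adjusted p and the library left out. Without *barc* RNAi 2 these were He (0.120), atilla (0.118), RnrS (0.117), CycA (0.0983), SdhC (0.0962), jim (0.0728), zip (0.0699) and SdhA (0.0655), and without *barc* RNAi 1 CG3605 (0.117), brat (0.0891), RpA-70 (0.0738) and Rpn5 (0.0524). Without control 1 they were Incenp (0.0922) and TotA (0.0794), without control 2 br (0.0715), x16 (0.0646) and EcR (0.0519), and without control 3 Ser (0.0655) and t-cup (0.0563). The libraries that ended a call numbered from 1 (t-cup) to 7 (CG3605).

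The third comparison asked which changes the 2 systems shared. Both showed a rise of TepIV (neuroblasts 3.73, SE 0.18, S2 cells 2.18, SE 0.55), of the detoxification gene Ugt86Di (2.35, SE 0.21, and 2.03, SE 0.16), of the EGF receptor ligand gene vn (1.71, SE 0.19, and 2.12, SE 0.39) and of CG18547 (4.19, SE 0.19, and 1.96, SE 0.34). In replicates 1 and 2 and in replicates 3 and 4 of the S2 cells, TepIV stood at 2.71 and 1.65, Ugt86Di at 2.01 and 2.04, vn at 2.44 and 1.79 and CG18547 at 2.49 and 1.43. The others among the 10 shared genes with the largest smaller change also rose in both. They were CG9865, CG33057, CG8620, CG15784, CG14855 and the non-coding CR43264 (105 ± 4.26 to 415 ± 0.536 FPKM in neuroblasts, 1001 ± 421 to 3578 ± 1804 FPKM in S2 cells). The S2 call of CG8620 ended without control 3 (adjusted p = 0.0938), as did that of TepIV (0.0620). CG9865, CG33057 and CR43264 overlap other genes. Cdk9 and sip3 fell and rad50, unc-13 and fd59A rose in both systems, at the values given above.

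Of 6298 genes tested in both systems, 255 rose in both, where independent lists would share 120.6, and 450 fell in both, where they would share 220.7 (Fisher's exact test, p = 2.0e-39 and 6.6e-72). These p-values treat genes as independent, which they are not, and do not measure the spread between libraries. Opposite calls numbered 127, with 327.6 for independent lists. Log2 fold changes in the 2 systems had a Pearson r of 0.37 and a Spearman rho of 0.38 across genes, which are not independent replicates. The 705 genes called the same way became 1120 with the first number as a block, 1546 with S2 replicates 1 and 2 alone and 256 with replicates 3 and 4 alone, beside 226, 484 and 63 opposite calls. Leaving out S2 control 1, 2 or 3 left 453, 410 or 461, leaving out S2 *barc* RNAi 1 or 2 left 413 or 391, and 1 fit over all 4 groups gave 123.

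**Figure D3:**
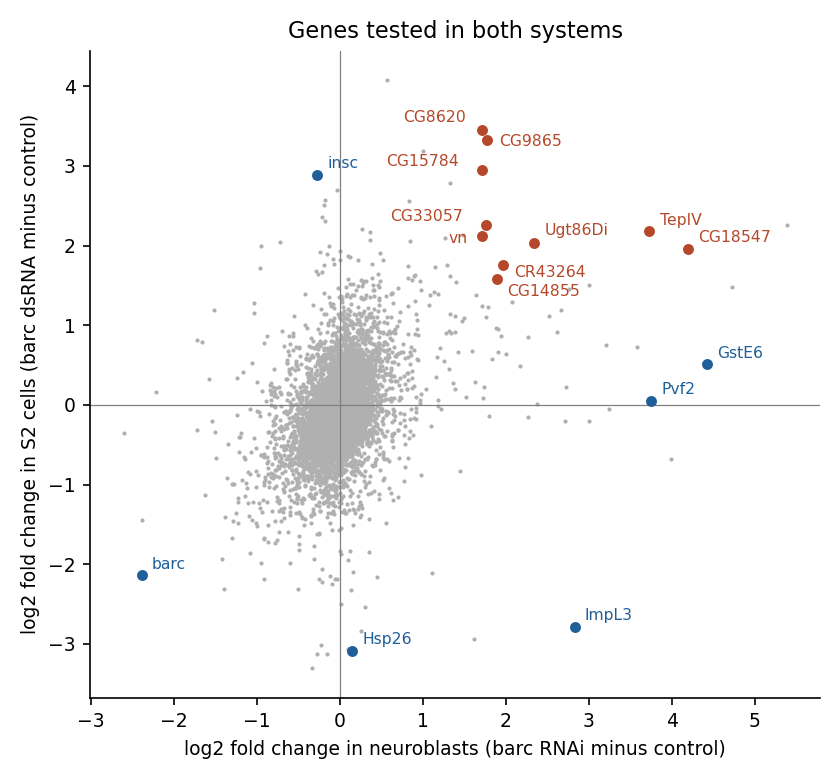
Log2 fold change in neuroblasts (horizontal axis) against S2 cells (vertical axis) of the 6298 genes tested in both, 1 dot per gene. The 10 shared genes are red, and *barc*, Hsp26, ImpL3, Pvf2, GstE6 and insc are blue, with Hsp26 at 0.15 and -3.08 and Pvf2 at 3.75 and 0.05.

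The last comparison tested, gene by gene, whether the effect of *barc* RNAi differed between the systems. Neuroblast controls carried an empty landing site, while S2 controls received double-stranded RNA against mCherry. The neuroblast contrast, and so the difference, does not separate the loss of *barc* from other effects of RNAi itself. ImpL3 differed most among named genes, by 5.61 (adjusted p = 0.0025), rising in neuroblasts and falling in S2 cells. Pvf2 rose in neuroblasts and stood at 170 and 178 FPKM in S2 cells, a difference of 3.70 (SE 0.33, adjusted p = 4.3e-04). Hsp22 rose in neuroblasts and fell in S2 cells (difference 4.56, SE 0.44), and Hsp26 differed by 3.23 (SE 0.34), with 878 and 973 FPKM in neuroblasts. Hsp22 overlaps Hsp67Bb and has no value in the authors' tables, so its difference is uncertain. The adhesion gene Nrt was lower in the neuroblast effect (difference -2.49, SE 0.22), at -0.17 in neuroblasts and 2.31 in S2 cells, as was CG34430, listed at 0 in both *barc* RNAi neuroblast libraries and at 2.51 and 2.06 FPKM in the controls. Others with the smallest p were CG3251 (3.30), alphagamma-element:CR32865 (2.12), CG17803 (-1.80), Sep4 (-1.62) and CG7267 (-1.57).

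Among the fixed lists, heat shock (median difference 2.52, camera adjusted p = 1.4e-14), glycolysis (1.08, 1.5e-10), ribosome biogenesis (-0.37, 3.2e-07) and temporal factors (-0.60, 0.025) differed between the systems. With an estimated correlation none of the 4 passed (adjusted p = 0.197, 0.155, 0.155 and 0.726 with an estimated correlation). The differences of the G1/S list (0.34, adjusted p = 0.0681), the p53 list (-0.10, 0.512), neuron markers (-0.65, 0.145) and glial markers (-0.32, 0.105) did not pass. In all, 227 of 6298 genes differed, 136 higher and 91 lower in neuroblasts, and the replicate block gave 360. This count was 50 and 40 without neuroblast control 1 and 2, 45 and 51 without neuroblast *barc* RNAi 1 and 2, 150 without S2 *barc* RNAi 2, 730 without S2 control 4 and 630 with no filter on low values.

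**Figure D4:**
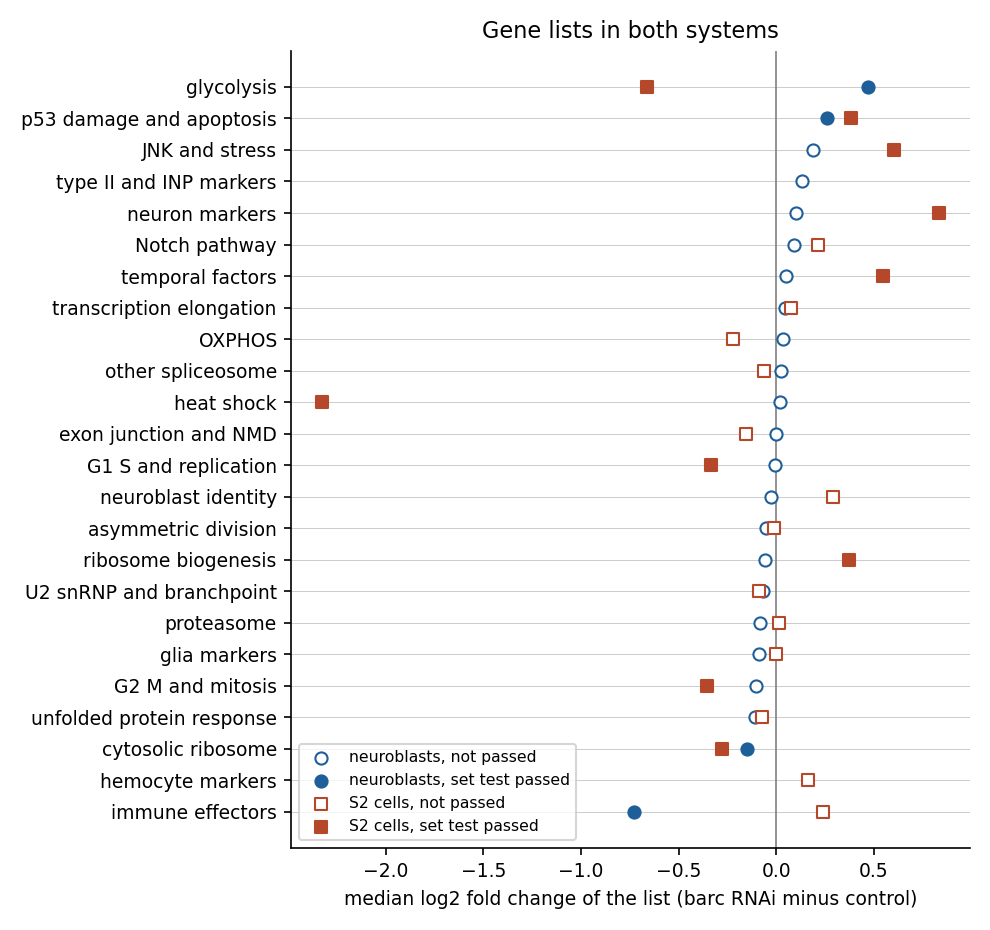
Median log2 fold change of each gene list after *barc* RNAi, with circles for neuroblasts and squares for S2 cells, filled where camera with the preset correlation passed. Glycolysis lies at 0.47 in neuroblasts and -0.66 in S2 cells, and heat shock at 0.02 and -2.33.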

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

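In this part the tests chosen only after the result was seen are the count of gene calls over other splits of the S2 libraries, the comparison of the *barc* falls between the pairs of S2 replicates, the odds ratio and the comparison of markers of other cells, and the other tests were chosen before.

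In 206 groups of 4 S2 libraries, each 1 named gene in 1 group, 3 groups (1.46%) held a library far from the others by Dixon's critical value for 4 samples. Chance gives about 1 in 20 where 4 libraries can be exchanged freely, which the pairs by first number make doubtful here. In S2 control 4, Sulf1 stood at 15.5 FPKM against 6.71 to 7.77 in the other controls, and EcR at 24.4 FPKM against 14.8 to 15.96. In S2 control 2, atilla stood at 0.275 FPKM against 0.0559 to 0.0696.

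The effect of *barc* RNAi differed between neuroblasts and S2 cells for 39 of the 148 named genes tested in both (interaction test, highest adjusted p = 0.0481, Nnp-1), against 227 of all 6298 genes. The named genes were picked for large changes or small interaction p, so their share is no measure of how common such differences are. The neuroblast effect lay below the S2 effect for insc (-3.16), spdo (-2.74), ogre (-2.73), CG34430 (-2.53), Nrt (-2.49), CecA1 (-2.45), fog (-2.37), RpS6 (-2.25), rpr (-1.93), Scgdelta (-1.91), CG17803 (-1.80), Sep4 (-1.62), CG7267 (-1.57), N (-1.24), CG7757 (-1.02), mbm (-0.80), Nnp-1 (-0.68) and RpI1 (-0.67). The difference of RpS6 is uncertain, since its neuroblast change was -2.60 by FPKM but -0.34 in the authors' table, against -0.35 by FPKM in S2 cells. It lay above for genes of glycolysis and lactate production, Pgi (1.05), Pglym78 (1.08), Gapdh1 (1.48), Eno (1.502), Tpi (1.87), Pfk (2.04) and ImpL3 (5.61), and for heat shock genes, Hsp70Bbb (2.61), Hsp27 (2.80), Hsp70Bb (2.97), Hsp68 (2.97), Hsp70Ba (3.10), Hsp70Bc (3.16), Hsp26 (3.23) and Hsp22 (4.56). The same held for alphagamma-element:CR32865 (2.12), Gadd45 (2.46), CG3251 (3.30), Pvf2 (3.70), GstE6 (3.92) and Nha2 (4.67). Among the fixed lists, heat shock (2.52) and glycolysis (1.08) lay higher in neuroblasts and temporal factors (-0.60) and ribosome biogenesis (-0.37) lower, by median difference and camera with the preset correlation. None of the 4 passed with an estimated correlation (adjusted p = 0.197, 0.155, 0.726 and 0.155).

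For the 2030 genes called in S2 cells, 1 of the 35 splits of the 8 libraries into 4 and 4, the real split, gave as many calls, and the highest other split gave 562. This share lies under 0.05, but it measures chance only where the 8 libraries can be exchanged freely. The split with 562 follows the first number of the sample descriptions, which speaks against free exchange, so chance is not excluded by this count. With this number as a block 18 splits remain, too few for a share under 0.05, and the real one called 3496 genes and the highest other 0 (limma, 2469 at an unadjusted p under 0.05). For the 10 gene lists, 5 of the 35 splits gave as many, with 12 in the highest other split, so chance cannot be excluded for the number of lists. Among the 8 splits that part every pair of equal replicate numbers, again too few, the highest other count of genes was 0 (limma, at most 1296 at an unadjusted p under 0.05) and 2 splits, the real one included, gave at least 10 lists.

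The S2 effect of *barc* RNAi differed between replicates 1 and 2 and replicates 3 and 4 for 1702 of 7603 genes (2827 at an unadjusted p under 0.05), among them by the lists of G1/S (median difference 0.82, camera adjusted p = 1.5e-08), G2/M (0.88, 8.5e-11), oxidative phosphorylation (0.67, 6.7e-05), glycolysis (0.65, 0.0020), proteasome (0.46, 0.0014), JNK (-0.58, 0.0048), neuroblast identity (-0.50, 0.0145) and p53 (-0.11, 0.0145), none of which passed with an estimated correlation (lowest adjusted p = 0.275). A weaker knockdown in replicates 3 and 4, where the effects were smaller, is argued against by *barc* itself, whose change there lay lower by -0.63 (SE 0.28, limma adjusted p = 0.144). Scaling as the whole cause is argued against by 1493 genes with quantile normalisation (1228 of them among the 1702). Whether 1 control stands apart stays open, since the count was 924, 706, 4118 and 3168 without control 1, 2, 3 and 4 (and 648, 810, 668 and 756 without *barc* RNAi 1, 2, 3 and 4), and leaving out control 3 or 4 also removes the spread between them (chi-square per degree of freedom 70.3). What the first number stands for, such as a day, a sequencing batch or a separate treatment with double-stranded RNA, stays open, and no biological explanation was tested.

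Of the 117 genes at least 2-fold higher in *barc* RNAi neuroblasts, 84 were tested in S2 cells, where 39 were called higher (46.4%, against 601 of the 6214 other genes, 9.67%) and 3 lower, with a median of 0.91. A genetic difference between the fly lines, which S2 cells lack, is argued against for the shared part by this odds ratio of 8.09 (95% interval 5.09 to 12.8). For the 78 genes not called higher in S2 cells it stays open, since 30 lie on arm 2R (38.5%, against 20.2% of tested genes, a ratio of 1.90, Fisher p = 1.8e-04, adjusted p = 0.0011), of which 12 lie within 20 kb of another, including 3 glutathione S-transferase and 2 cytochrome P450 genes. More RNA from glia in the sort is argued against by the glial markers, of which 0 of 6 rose and 2 fell. For hemocytes and fat body it stays open, since only 3 and 1 of their markers were tested. The mean log2 fold change of glial, hemocyte and fat body markers together (-0.20, SD 0.37, n = 10) lay below that of neuron markers (0.24, SD 0.51, n = 11) by -0.45 (exact permutation p = 0.0250). The permutation was over marker genes, which are not independent replicates. It compared these markers with neuron markers and did not test whether their mean lay below 0. A lower share of neuroblasts with more neurons in the sort stays open, since the mean of the neuron markers lay above 0. A change in the neurons among the sorted cells and an effect of *barc* RNAi in neuroblasts also stay open.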

How the results depend on the processing

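In this part 1 test, the fits that kept failed and low-data estimates, was chosen only after the data were seen, and it changed no call of a named gene.

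The fall of *barc* kept its direction and call under every alternative run, from -2.50 to -2.15 in neuroblasts (highest adjusted p = 0.0012) and from -2.46 to -1.54 in S2 cells (0.0047), beside -2.64 and -2.23 in the authors' tables. Where leaving out a library left 1 in a group, that library was assumed to vary like the others. Neuroblast genes numbered 1847 to 2959 when 1 library was left out, against 2888 with all, with 1847 without control 1 and 1897 without control 2. In 1 fit over all 4 groups they numbered 356, and 123 genes changed the same way in both systems. S2 genes numbered 1104 to 2513 (without control 4) against 2030, with 1253 and 1146 without control 1 and 2 and 1154 and 1104 without *barc* RNAi 1 and 2. With the first number as a block they were 3496, and 5460 within replicates 1 and 2 and 927 within replicates 3 and 4. Genes changed the same way in both systems numbered 391 to 810 (without S2 control 4) against 705, with 453, 410 and 461 without S2 control 1, 2 and 3 and 413 and 391 without S2 *barc* RNAi 1 and 2. In the 3 first-number fits they were 1120, 1546 and 256. Genes whose effect differed between the systems numbered 40 to 730 against 227, with 50 and 40 without neuroblast control 1 and 2, 45 and 51 without neuroblast *barc* RNAi 1 and 2, 150 without S2 *barc* RNAi 2 and 730 without S2 control 4. That count was 630 with no filter and 360 with the replicate block. Camera with an estimated correlation passed 0 of 23 lists in neuroblasts (0 at an unadjusted p under 0.05) and 0 in S2 cells (1 unadjusted), and fry passed 0 in neuroblasts (9 unadjusted) and 8 in S2 cells (9 unadjusted), against 4 and 10 by camera with the preset correlation. By fry, heat shock (adjusted p = 0.0040), ribosome biogenesis (0.0090), glycolysis (0.0108) and JNK (0.032) passed in S2 cells. So did neuron markers (0.032), glial markers (0.032), neuroblast identity (0.038) and p53 (0.039), of which glial markers and neuroblast identity had not passed camera. Temporal factors (0.135), G1/S (0.226), cytosolic ribosome (0.231) and G2/M (0.268) passed camera but not fry. Within replicates 3 and 4 the medians of the G1/S and G2/M lists turned to 0.0909 and 0.0513. Lsp1gamma in neuroblasts, not called, ran from -0.0084 without control 1 to 0.0877 without control 2. Leaving out a library lowers the number of samples, and the fits within pairs use 4 libraries; for the other changed results the cause was not tested. The authors' deposited table called 1379 genes higher and 675 lower in S2 cells, against 876 and 1154. Of the other values, 3861 for single genes and lists kept direction and side of the threshold, 352 fell below it, 19 rose above it and 3 reversed, and for the main results 138 stayed, 23 were weaker and 7 stronger. The libraries held between 14.6 M and 48.7 M implied fragments (M stands for 1000000), which limits the measure of low transcripts.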

Other observations

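In this part the gene families and the tests of ribosomal protein genes among the partners with introns and of intron number were chosen only after the result was seen, and the tests of matched genes in both systems were chosen before.

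Several genes of detoxification enzymes, families picked because of their values, for which a group test would be circular and is not given, rose in *barc* RNAi neuroblasts. Of 12 glutathione S-transferase genes tested 10 rose, 6 of them at least 2-fold, and 1 fell (GstS1, -0.42), with a median log2 fold change of 1.09. Beside those named in the report, GstE5 (2.30), GstE7 (2.27), GstD3 (1.84) and GstD6 (1.28) rose. These genes lie in clusters of close copies, so single values are uncertain. Of 8 cytochrome P450 genes 6 rose, with a median of 0.56, among them Cyp4p1 (3.05), Cyp12a4 (1.46) and Cyp12c1 (0.58). Both UDP-glucuronosyltransferase genes tested rose, Ugt86Di (2.35) and Ugt86Da (1.40). Of the genes that rose, 4 of 10, 4 of 6 and 2 of 2 in these families lay below 1 FPKM in the controls and passed the filter through their level after RNAi, which favours rises in these counts. The medians of the first 2 families kept their sign under each scaling, at 0.96 to 1.34 and 0.48 to 0.69.

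In S2 cells these families went both ways. Of 36 cytochrome P450 genes 10 rose and 3 fell (median 0.07, from 0.03 to 0.16 over the scalings), with Cyp6d2 (5.02), Cyp6w1 (2.18) and Cyp6a20 (1.06) rising. Of 17 glutathione S-transferase genes 2 rose, GstE1 (1.60) and GstS1 (1.00), and 3 fell, GstE9 (-1.62), GstE2 (-1.30) and GstE8 (-0.95), with a median of 0.51 (0.51 to 0.65 over the scalings). Of 6 UDP-glucuronosyltransferase genes 3 rose, Ugt86Di (2.03), Ugt86Da (1.54) and Ugt35a (1.43), and 1 fell, Ugt58Fa (-1.85), with a median of 1.04 (0.92 to 1.19). In replicates 1 and 2 the medians of these 3 families, in the order given, were 0.43, 0.62 and 1.40. In replicates 3 and 4 they were 0.08, 0.31 and 0.80. Of 72 genes of mitochondrial ribosomal proteins 1 rose and 9 fell in S2 cells, with a median of -0.30 (-0.30 to -0.18 over the scalings). The medians were -0.52 in replicates 1 and 2 and -0.01 in replicates 3 and 4. In neuroblasts 14 of 71 rose and 19 fell, and the median of -0.02 turned to 0.08 after rescaling to TPM.

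Since Tat-SF1 takes part in splicing, a hypothesis was that genes with introns lose more transcript than intronless genes when *barc* is low. In neuroblasts, genes with introns lay lower than intronless genes matched on level and transcript length by a median of -0.11 (95% interval -0.148 to -0.056, permutation p = 0.0005, the smallest that 2000 shuffles give), and by -0.10 without cytosolic ribosomal protein genes. The intervals and permutation p-values of this test are over genes and do not measure the spread between libraries. In S2 cells the difference was -0.13 (-0.212 to -0.068, permutation p = 0.0005, again the smallest) and -0.12 without those genes, with -0.16 in replicates 1 and 2 (permutation p = 0.0035) and -0.12 in replicates 3 and 4. Without matching it was -0.03 in neuroblasts and 0.01 in S2 cells, so it rests on the matching, with 576 and 656 intronless genes and transcript length itself tied to the change (Spearman rho 0.18 and 0.27). Intron number rose with the change (rho 0.07 and 0.17), which runs against the hypothesis, and among genes with introns, given level and length, the partial rho was -0.02 and 0.02, so the hypothesis stays open, and splicing itself was not measured here.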
